A study of Homo sapiens with 10 samples.

How the data were processed

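RNA was measured by sequencing in 10 libraries of the CRL-4003 line, 3 per ligand after 24 h of KYN or TCDD and 2 per ligand after 6 d. Per the labels, the cells were decidualized for 2 days before the ligand was added and media and ligand were renewed during the exposure, RNA was isolated with a column kit and libraries followed a standard Illumina protocol. Per the submitters' processing notes, bases were called with CASAVA 1.4, and TopHat2 2.0.5 and HTSeq (no version given) were used with genome build GRCh37. The notes do not state the strand of counting or the annotation release. The deposited table held raw counts per Ensembl gene, 1 count column per library, made by the authors with HTSeq per the file name, beside columns that the authors headed TPM.

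The deposited TPM values were used in no test. Those of 1 and above had lost their decimal separator, so about 80% of the values, zeros among them, could be read. The pattern of zeros in each TPM column matched a count column exactly, but 5 of the 10 TPM columns, all of 24 h, matched the counts of another replicate of the same group, so the replicate numbers differ between the count and the TPM columns while the groups do not. Replicate numbers here are those of the count columns.

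The table held 60379 genes, of which 28136 had at least 1 read and 14858 passed edgeR's filterByExpr (minimum count 10) and were tested. The filter kept 99.95 to 99.96% of the counts of each library. Counts were normalized by TMM, with factors of 0.963 to 1.029, and the 10 most abundant genes held 5.27 to 6.73% of the counts. A quasi-likelihood model with 1 mean per group was fitted to all 10 libraries in edgeR 4.0.16 under R 4.3.3, with a common biological coefficient of variation of 0.0755 and 5.68 prior degrees of freedom. From it came 7 comparisons: TCDD against KYN at 24 h, at 6 d and averaged over the times, 6 d against 24 h with KYN, with TCDD and averaged over the ligands, and the interaction of ligand and time. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Log2 fold changes carry a standard error or a 95% confidence interval built on it. The standard error is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It may be too small where a change is large and a group has few reads. CPM (scaled with TMM factors) are given as mean ± SD over libraries. Principal components were taken from log2 CPM with a prior count of 2. Genes with 3 or fewer reads in a group are described by reads or CPM without a fold change.

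The comparisons, the 31 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the genes named in a comparison are the 8 with the largest and the 8 with the smallest log2 fold change (5 and 5 for the interaction) among those that passed, had a mean of at least 2 CPM and showed no overlap between the libraries compared within a time or within a ligand, passing over clone names, antisense genes, pseudogenes and host genes of small RNAs. Up to 4 members of each described list with the smallest p are named as well, and AHRR, TIPARP, AHR, PRL and IGFBP1 were always to be looked at, as were CYP1A1 and CYP1B1. MT1G and PGR were named after their values were seen.

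The lists covered AHR target genes, the AHR receptor complex and partners, tryptophan and kynurenine metabolism, amino acid transporters, decidualization markers, cAMP responsive genes, progestin and glucocorticoid responsive genes, steroid and retinoid metabolism, and WNT pathway genes. Others covered TGF-beta and BMP response, collagens and matrix, matrix metalloproteinases and inhibitors, complement and coagulation, cytokines and chemokines, NF-kappaB response genes, interferon stimulated genes, and HLA and antigen presentation. The stress and metabolism lists were NRF2 target genes, ATF4 and integrated stress response, secretory pathway and unfolded protein response, p53 target genes, cell cycle genes, glycolysis and hypoxia response, and cholesterol biosynthesis. Smooth muscle and myofibroblast, epithelial, endothelial and leukocyte markers, replication-dependent histone genes, mitochondrially encoded genes and ribosomal protein genes served to look for other cells and for differences in RNA quality. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated per list and with fry. None of the lists called with the preset correlation passed with the estimated one.

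Alternatives were DESeq2 1.42.0 size factors, its Wald test, limma-voom, no count filter, a filter at 1 CPM in 3 samples, a block on the replicate number, a fit of the groups compared alone, and leaving out each library in turn. Others were added after seeing the data and are named with their effect. Recovery by edgeR was checked on simulated data with 200 changed genes. At 24 h between ligands it recovered 85% of changes of 1.5-fold and 98% of changes of 2-fold (10 false among 193 calls). At 6 d it recovered 72% and 95% (9 false among 176). Between times averaged over ligands it recovered 96% and 99% (16 false among 211). The simulation drew genes independently and changed only genes of at least 2 CPM. It lacked structure shared across genes, such as the 2 sets of 24 h libraries, so recovery and false calls in the real data may differ.

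Gene types, lengths, GC content and exon overlaps came from GENCODE v29, which held 96.5% of the tested genes. It describes another genome build than the one used for counting, so no coordinates are given. ChIP-seq of the same series and control libraries of another series were not analysed here. Drawings were made with Python 3.11.15 and matplotlib 3.10.9.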

Results

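The libraries measured mRNA in CRL-4003, an established human endometrial stromal fibroblast line. The cells had been decidualized in culture with cAMP and a progestin (MPA), a treatment that drives stromal fibroblasts toward the secretory state of the uterine lining in early pregnancy. After 2 days of decidualization they received an activator of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. The activator was either L-kynurenine (KYN), a breakdown product of tryptophan, at 100 µM, or the dioxin TCDD at 10 nM. Cells were collected after 24 h of ligand, at 3 days of decidualization, with 3 libraries per ligand, or after 6 days (6 d), at 8 days of decidualization, with 2 libraries per ligand. Total counts per library ran from 24110046 to 37697229 for KYN at 24 h, from 32514501 to 37607372 for TCDD at 24 h, from 31136145 to 34011857 for KYN at 6 d and from 28028694 to 29365439 for TCDD at 6 d. The comparison of times joins the length of ligand exposure with the length of decidualization, and the comparison of ligands sets different doses side by side. Untreated control libraries that the series names were not analysed here, so no comparison measures a ligand against its absence. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

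Time separated the libraries more than ligand did. The first principal component of log2 CPM held 76.7% of the variance and placed the 6 libraries of 24 h between -45.5 and -36.5 and the 4 libraries of 6 d between 61.9 and 65.1. Among the 6 libraries of 24 h alone the first component (45.4% of the variance) did not follow the ligand, with 24hKYN 1, 24hKYN 2 and 24hTCDD 2 at -21.3, -21.4 and -18.1 and 24hKYN 3, 24hTCDD 1 and 24hTCDD 3 at 8.9, 25.1 and 26.7. Among the 4 libraries of 6 d it did (42.1%), with KYN at -16.1 and -14.9 and TCDD at 11.9 and 19.1.

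**Figure D1:**
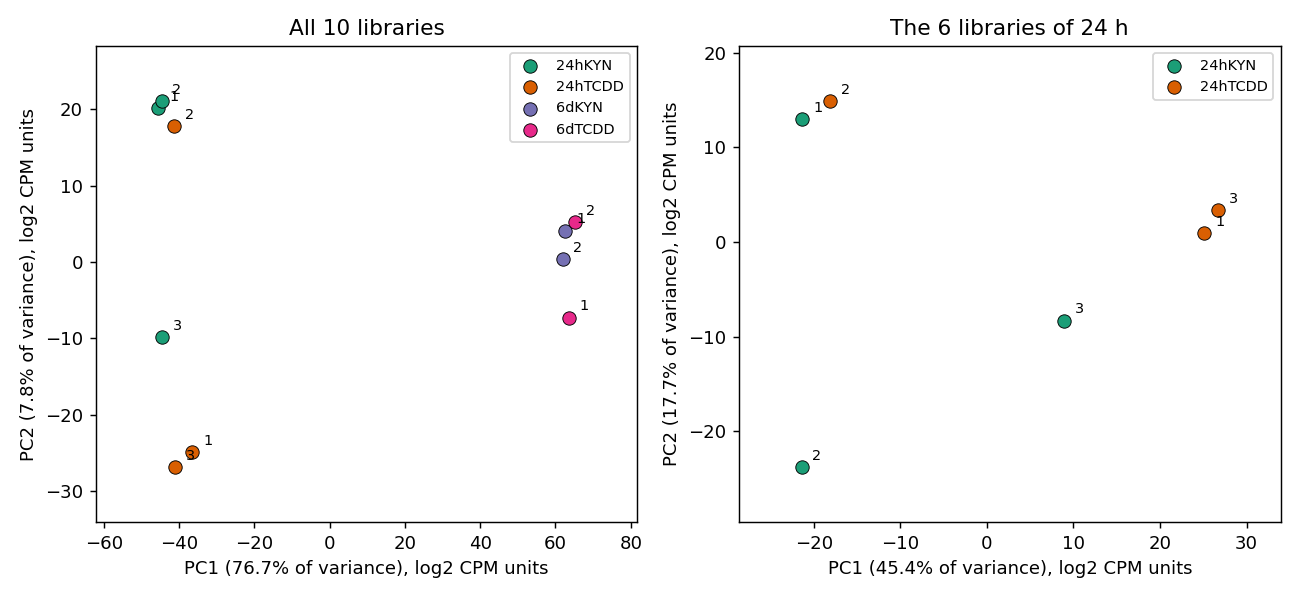
Principal components of log2 CPM, in log2 CPM units, for all 10 libraries (left) and for the 6 libraries of 24 h (right), with 1 point per library and its replicate number beside it. On the left the libraries of 6 d lie at 61.9 or more on the first component, and on the right 24hTCDD 2 lies with 24hKYN 1 and 24hKYN 2.

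The comparison of TCDD with KYN at 24 h asked how the responses to both ligands differ early. MT1X and MT1E, which encode metal-binding metallothioneins, were lower with TCDD. MT1X (ENSG00000187193) stood at 8.77 ± 1.8 CPM (mean ± SD, n = 3) with KYN and 2.93 ± 0.49 CPM with TCDD, a log2 fold change of -1.58 ± 0.17 (SE). MT1E (ENSG00000169715) stood at 17.2 ± 2.8 CPM with KYN and 7.83 ± 1.2 CPM with TCDD (-1.14 ± 0.13). DIO2 (ENSG00000211448), the deiodinase that activates thyroid hormone, was lower too, at 18.2 ± 1.3 CPM against 28.4 ± 1.5 CPM (-0.64 ± 0.07). These were the 3 of 14858 tested genes that passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p of 0.00759 for MT1X, 0.0114 for MT1E and 0.00759 for DIO2. In each of them all 3 KYN libraries lay above all 3 TCDD libraries, a separation that chance gives for 10% of genes. Metallothionein genes are near-identical copies that share reads, so the split of reads between them is uncertain.

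No canonical AHR target passed over all genes between the ligands at 24 h in edgeR. AHRR, the receptor's repressor, stood at 24.9 ± 0.72 CPM with KYN and 25.8 ± 1.6 CPM with TCDD, a log2 difference of 0.05 with a 95% confidence interval of -0.11 to 0.22. TIPARP, a member of the poly(ADP-ribose) polymerase family induced by dioxin, stood at 109 ± 9.2 and 138 ± 14 CPM (0.35 ± 0.08, interval 0.17 to 0.52, edgeR adjusted p = 0.178). AHR itself stood at 28.8 ± 1.7 and 27.7 ± 2.2 CPM. CYP1A1 and CYP1B1, the classical AHR-induced cytochrome P450 genes, had 24 and 10 reads over all 10 libraries and at most 5 and 4 in any of them. They did not pass the count filter, so no difference in them was detectable at this depth. Of the 12 tested AHR target genes 2 (TIPARP and SERPINB2) were higher with TCDD when adjusted over the list alone (camera adjusted p = 0.054; adjusted p = 0.513 with an estimated correlation).

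Genes that respond to progestins and glucocorticoids were lower with TCDD than with KYN at 24 h as a group. Of 15 tested members 2 were lower over all genes, MT1X and MT1E, and 9 were lower when adjusted over the list alone (camera adjusted p = 5.36e-24; adjusted p = 0.0697 with an estimated correlation). The next members by p were MT2A, another metallothionein (-0.71 ± 0.11, adjusted p = 0.105), and ERRFI1, a feedback inhibitor of EGF receptor signalling (-0.33 ± 0.06, adjusted p = 0.134 in edgeR). Decidualization markers were lower as a group, with DIO2 lower of 28 tested and 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 1.17e-06; adjusted p = 0.339 with an estimated correlation). Their mean log2 CPM per library, relative to the mean of all libraries, did not separate the ligands, with 24hTCDD 2 and 24hKYN 3 both at -0.3. Of the best known markers, PRL (prolactin) stood at 4.03 ± 0.073 CPM with KYN and 4.37 ± 0.22 CPM with TCDD, and IGFBP1 at 272 ± 45 and 224 ± 46 CPM, neither past the threshold. The count of 3 genes became 0 without 24hKYN 1, 5 without 24hTCDD 1, 367 without 24hTCDD 2 and 0 without 24hTCDD 3. It was 101 with DESeq2, 425 with no count filter and 0 in a fit of the 24 h libraries alone.

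At 6 d the ligands differed in fibrillar collagen genes and in PDK4, KDR and HMOX1. COL1A1, a chain of type I collagen, stood at 4130 ± 480 CPM (mean ± SD, n = 2) with KYN and 7070 ± 270 CPM with TCDD, a log2 fold change of 0.78 ± 0.10. COL1A2 (0.54 ± 0.08) and COL3A1 (0.49 ± 0.08) were higher with TCDD as well. PDK4, a kinase that restrains pyruvate dehydrogenase, was lower with TCDD at 3.03 ± 0.83 CPM against 11.6 ± 1.7 CPM (-1.93 ± 0.26). KDR, a receptor of VEGF, was lower at 15.3 ± 3.8 CPM against 40.1 ± 4.9 CPM (-1.39 ± 0.18). HMOX1, heme oxygenase, was lower at 31.3 ± 0.78 CPM against 42.9 ± 0.44 CPM (-0.45 ± 0.06).

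In all, edgeR called 22 genes between the ligands at 6 d, 16 higher and 6 lower with TCDD, and each separated the 2 KYN libraries from the 2 TCDD libraries. With 2 libraries per group chance separates many genes in this way, and genes that passed nearly always do. The separation therefore adds no support to the calls. The largest increases were those of PLXNC1, a semaphorin receptor (1.37 ± 0.23), SULF1, an extracellular sulfatase acting on heparan sulfate (0.84 ± 0.11), and STRA6, a retinol transporter (0.81 ± 0.13). FAM46C rose from 77.7 ± 7.2 to 132 ± 9.9 CPM (0.77 ± 0.10) and ITGBL1 by 0.70 ± 0.11, followed by CHN1 at 0.57 ± 0.06 and MRVI1 at 0.56 ± 0.08. The other genes lower with TCDD were TMEM140 (-1.07 ± 0.16), LACC1 (-0.78 ± 0.10) and CLU, the extracellular chaperone clusterin, at 2260 ± 25 CPM against 3050 ± 63 CPM (-0.43 ± 0.07). Adjusted p over these 14 genes with the largest changes ran from 0.0129 for CHN1 to 0.0431 for PLXNC1, STRA6 and ITGBL1 in edgeR. AHRR differed by 0.01 (95% confidence interval -0.19 to 0.21) and TIPARP by -0.15 (-0.36 to 0.06). PRL stood at 123 ± 0.078 CPM with KYN and 103 ± 3.2 CPM with TCDD (-0.25 ± 0.06, edgeR adjusted p = 0.177).

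**Figure D2:**
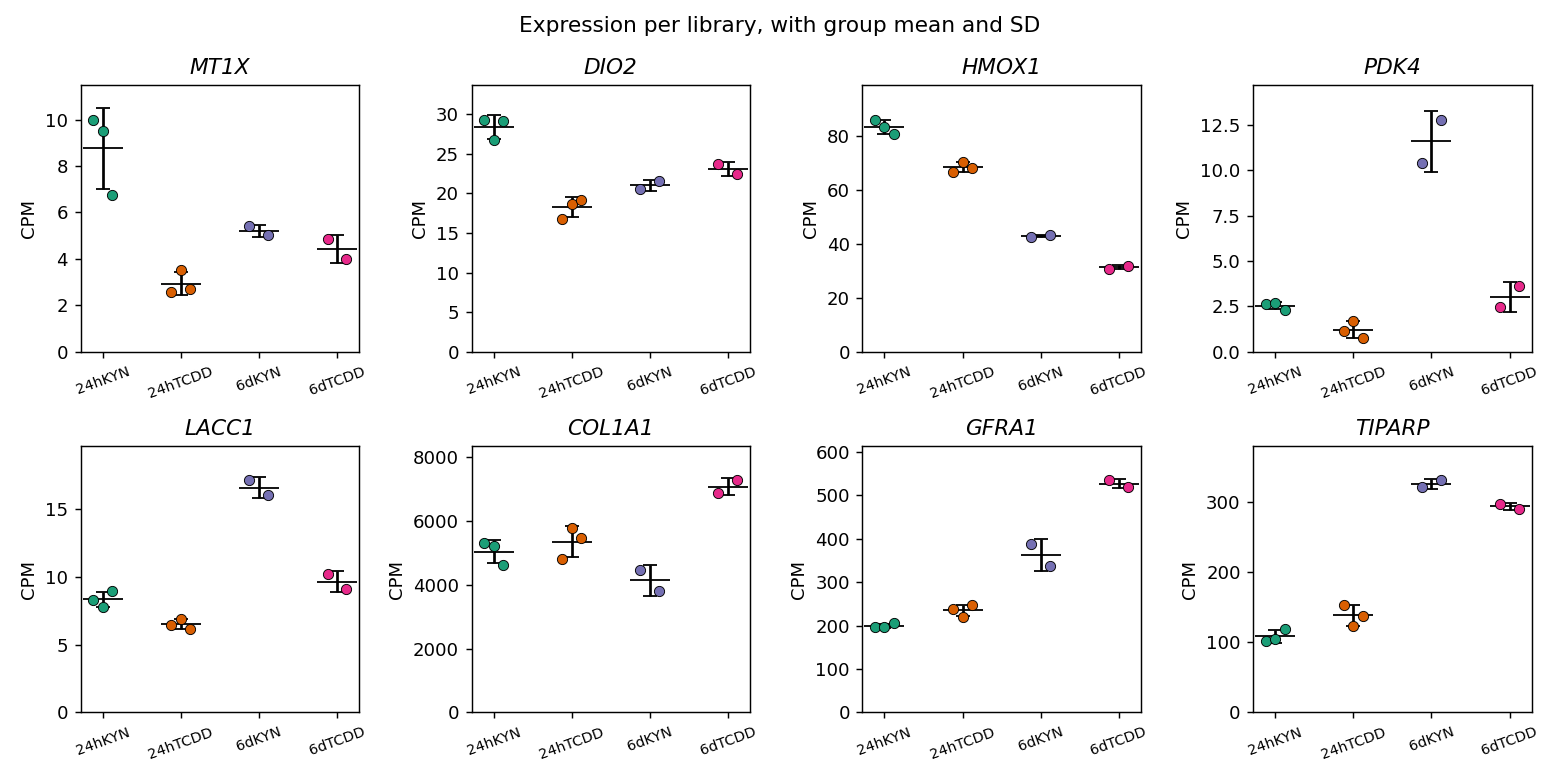
CPM per library (points) in the 4 groups for 8 genes, with the group mean (horizontal line) and SD (bars). MT1X and DIO2 were lower with TCDD at 24 h, PDK4, HMOX1 and LACC1 were lower and COL1A1 and GFRA1 higher with TCDD at 6 d, and TIPARP passed between the times but not between the ligands.

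Collagen and matrix genes were higher with TCDD at 6 d as a group. Of 30 tested members 3 were higher over all genes (COL1A1, COL1A2 and COL3A1), and 10 were higher when adjusted over the list alone (camera adjusted p = 1.25e-15; adjusted p = 0.0815 with an estimated correlation). None of 9 smooth muscle and myofibroblast markers passed over all genes in edgeR and 3 were higher when adjusted over the list alone (camera adjusted p = 9.64e-07; adjusted p = 0.157 with an estimated correlation), led by TAGLN (0.54 ± 0.10) and ACTA2 (0.39 ± 0.09). Of 18 WNT pathway genes the receptor FZD4 was higher (0.54 ± 0.08), over all genes and when adjusted over the list alone (camera adjusted p = 0.00976; adjusted p = 0.157 with an estimated correlation). Of 22 NRF2 target genes, which serve antioxidant defence, HMOX1 was lower by either adjustment, also when adjusted over the list alone (camera adjusted p = 1.31e-05; adjusted p = 0.0815 with an estimated correlation). Of 6 endothelial markers KDR was lower, over all genes and when adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.286 with an estimated correlation).

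The other 4 lists that passed camera at 6 d had no called member by either adjustment, over all genes in edgeR or when adjusted over the list alone. Of these p53 target genes (17 tested) and genes of ATF4 and the integrated stress response (23 tested) leaned lower with TCDD, at camera adjusted p of 4.14e-04 and 0.0173 (adjusted p = 0.0975 and 0.157 with an estimated correlation). Genes of cholesterol biosynthesis (21 tested) and ribosomal protein genes (34 tested) leaned higher, at camera adjusted p of 0.0182 and 0.0173 (adjusted p = 0.511 and 0.641 with an estimated correlation). AHR target genes had no called member of 12 in edgeR, nor when adjusted over the list alone (camera adjusted p = 0.228). The camera calls of WNT, ATF4 and ribosomal protein genes were lost without 6dKYN 1 and without 6dTCDD 2, that of cholesterol genes without 6dKYN 2 and without 6dTCDD 2, and that of endothelial markers without 6dKYN 2 and without 6dTCDD 1. The count of 22 genes fell to 0 without 6dKYN 1, 6dKYN 2 or 6dTCDD 2, to 1 without 6dTCDD 1 and to 13 without 24hKYN 1 or 24hTCDD 3, and rose to 47 without 24hTCDD 2. It was 99 with DESeq2, 206 with no count filter and 259 in a fit of the 6 d libraries alone.

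Averaged over both times, HMOX1, PDK4 and LACC1 were lower with TCDD and FAM46C, NF2 and GFRA1 higher. HMOX1 fell by 0.37 ± 0.04 on the log2 scale, PDK4 by 1.51 ± 0.18, and LACC1 by 0.57 ± 0.07, at an edgeR adjusted p of 0.013 each. Also lower were MT1X (-0.91 ± 0.13), TMEM140 (-0.68 ± 0.09), FAM129A (-0.47 ± 0.06), the lipid droplet protein gene PLIN2 (-0.34 ± 0.05) and TDP2 (-0.25 ± 0.04). Higher with TCDD were FAM46C (0.54 ± 0.07), FJX1 (0.39 ± 0.06), GFRA1, a receptor of GDNF (0.39 ± 0.05), the tumour suppressor NF2 (0.36 ± 0.05), the cell cycle regulator CCND1 (0.30 ± 0.05) and PDXK (0.29 ± 0.05). In total 9 genes were higher and 9 lower, and the 14 with at least 2 CPM whose libraries did not overlap within either time are the ones given. The metallothionein gene MT1G, singled out after its values were seen, was among the rest, at 0.436 ± 0.16 and 0.0683 ± 0.077 CPM with KYN and TCDD at 24 h and 1 ± 0.037 and 0.199 ± 0.033 CPM at 6 d.

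Averaged over both times, 3 of the lists that passed camera held a gene called over all genes. Collagens and matrix genes had 1 member higher of 30 and 12 when adjusted over the list alone (camera adjusted p = 2.08e-11; adjusted p = 0.142 with an estimated correlation). Progestin and glucocorticoid responsive genes had MT1X lower of 15 and 5 lower when adjusted over the list alone (3.38e-09; adjusted p = 0.165 with an estimated correlation). NRF2 targets had HMOX1 lower of 22 and 3 lower when adjusted over the list alone (camera adjusted p = 8.96e-04; adjusted p = 0.142 with an estimated correlation). Decidualization markers (8.4e-05; adjusted p = 0.275 with an estimated correlation), smooth muscle markers (0.0036; adjusted p = 0.343 with an estimated correlation) and cell cycle genes (0.012; adjusted p = 0.142 with an estimated correlation) passed camera with no member called over all genes in edgeR, and had 1 higher and 6 lower, 4 higher, and 1 higher when adjusted over the list alone. The median log2 difference was -0.13 for decidualization markers, 0.08 for smooth muscle markers and -0.12 for cell cycle genes. As a list, cell cycle genes thus leaned lower with TCDD despite the 1 member called higher. The camera call of cell cycle genes was lost without 24hTCDD 2. The count of 18 genes fell to 0 without 24hKYN 1 or any single library of 6 d, to 4 without 24hKYN 2 and to 2 without 24hTCDD 3, and rose to 45 without 24hKYN 3 and 177 without 24hTCDD 2. It was 177 with DESeq2 and 380 with no count filter.

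The ligand difference at 24 h and that at 6 d, which share no library, correlated weakly across the 14858 genes, with a Pearson r of 0.11 and a Spearman rho of 0.112; genes are not independent replicates, and r was -0.006 without 6dTCDD 1. Whether the difference between the ligands itself changed with time was tested as an interaction. For DIO2 the interaction was 0.77 ± 0.11 (edgeR adjusted p = 0.0844), for KDR -2.26 ± 0.36 (0.125), for MT1X 1.35 ± 0.27 (0.24), for COL1A1 0.69 ± 0.13 (0.239) and for TIPARP -0.49 ± 0.12 (0.367). None of the 14858 genes passed in edgeR, where 948 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0766. The count was 0 with limma-voom, 61 with DESeq2 and 250 with no count filter, and 51 in edgeR without 24hTCDD 2. A gene that passed at a single time is therefore not shown to differ between the times in its response to the ligands.

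Between 24 h and 6 d PRL, MMP10, EDNRB and AHR rose and APOL1 fell. PRL, the secreted hallmark of decidualization, rose from 4.03 ± 0.073 CPM (n = 3) to 123 ± 0.078 CPM (n = 2) with KYN and from 4.37 ± 0.22 to 103 ± 3.2 CPM with TCDD, and averaged over the ligands its log2 fold change was 4.75 ± 0.05. The stromelysin gene MMP10 rose by 8.28 ± 0.18 and the endothelin receptor gene EDNRB by 6.32 ± 0.10. APOL1, an apolipoprotein gene induced by interferon, fell by 5.36 ± 0.10, from 33.3 ± 1 to 0.812 ± 0.28 CPM with KYN. AHR rose by 1.18 ± 0.05, from 28.8 ± 1.7 to 67.3 ± 1.4 CPM with KYN and from 27.7 ± 2.2 to 60.9 ± 2 CPM with TCDD.

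Averaged over the ligands 9681 genes (65.2% of those tested) passed in edgeR, 4795 higher and 4886 lower at 6 d. Of these 1221 rose and 1146 fell over 2-fold, and 767 changed over 4-fold. Other large increases were C8orf4 (7.31 ± 0.07) and PMEPA1, a feedback inhibitor of TGF-beta signalling (6.38 ± 0.12). PDGFB, CMKLR1, CXCR4 and A2M rose from 1 to 14 reads per group at 24 h to between 404 and 876 reads per group at 6 d. Beside that of APOL1 the largest decreases were those of CCDC85A (-5.71 ± 0.20), the natriuretic peptide receptor gene NPR1 (-4.27 ± 0.16) and the DNA glycosylase gene NEIL3 (-4.19 ± 0.20). Then came the adrenergic receptor gene ADRA1B (-3.94 ± 0.19), IFI44L (-3.92 ± 0.13), the bradykinin receptor gene BDKRB1 (-3.84 ± 0.21) and the replication gene CDC45 (-3.83 ± 0.14). Adjusted p for these genes lay at 1.03e-08 (BDKRB1) or below in edgeR, with the libraries of 24 h and 6 d apart under each ligand. For genes with few reads at either time, such as C8orf4, PMEPA1, CCDC85A and NEIL3, the standard errors may be too small.

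With KYN 8064 genes passed between the times, 4034 higher and 4030 lower, and with TCDD 7824, 3906 higher and 3918 lower. Of these 3361 rose and 3338 fell with both ligands, against 1060.5 and 1062.7 for independent lists, and 9 passed in opposite directions. Both comparisons span the same days of decidualization and come from the same fit, so independence of the lists was not a likely outcome. The log2 fold changes with KYN and with TCDD, which share no library, had a Pearson r of 0.913 across genes. COL11A1 was among the largest decreases with KYN (-3.97 ± 0.19), UBA7 among those with TCDD (-3.90 ± 0.15) and MAOB, monoamine oxidase B, among the largest increases with TCDD (6.33 ± 0.24). AHRR stood between 24.9 and 27.4 CPM in all 4 group means (0.11 ± 0.06 between the times, edgeR adjusted p = 0.128).

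Decidualization markers moved in both directions, with 15 of 28 tested higher and 10 lower at 6 d (camera adjusted p = 0.00192; adjusted p = 0.259 with an estimated correlation). Beside PRL, the cytokine gene IL11 rose by 5.74 ± 0.14, MAOB by 5.80 ± 0.16 and BMP2 by 4.01 ± 0.06, while TIMP3, a metalloproteinase inhibitor, fell by 2.88 ± 0.09, IL15 by 1.83 ± 0.07, and the progesterone receptor gene PGR, singled out after its values were seen, by 1.10 ± 0.07. IGFBP1 did not pass (0.04 ± 0.11). Of 15 cAMP responsive genes 12 rose and 1 fell (camera adjusted p = 1.37e-08; adjusted p = 0.0757 with an estimated correlation), among them RGS2 (3.65 ± 0.09), SIK1 (2.23 ± 0.06) and PDE4B, a phosphodiesterase that degrades cAMP (1.91 ± 0.07). Of 15 progestin and glucocorticoid responsive genes 12 fell and 2 rose (7.54e-07; adjusted p = 0.147 with an estimated correlation), with SGK1 at -1.09 ± 0.05 and FKBP5 at -1.30 ± 0.06. Of 17 genes of steroid and retinoid metabolism 10 rose and 5 fell (camera adjusted p = 0.0462, a call lost without 24hTCDD 3, 6dKYN 1 or 6dTCDD 1; adjusted p = 0.238 with an estimated correlation). HSD17B2, which oxidizes estradiol to estrone, rose by 5.89 ± 0.12, and the retinol binding protein gene RBP1 by 4.38 ± 0.12, while the glucocorticoid receptor gene NR3C1 fell by 1.12 ± 0.04. For these and all other lists in the comparison of times the counts adjusted over the list alone equalled those over all genes, except that 10 collagens were higher, 7 AHR complex genes were lower, and 4 ribosomal protein genes were higher and 1 lower.

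All 21 genes of cholesterol biosynthesis were lower at 6 d (camera adjusted p = 9.15e-11; adjusted p = 0.1 with an estimated correlation), led by INSIG1 (-1.51 ± 0.04) and HMGCS1, HMG-CoA synthase (-1.51 ± 0.05). Of 26 genes of the secretory pathway and the unfolded protein response 23 rose and 2 fell (6.47e-05; adjusted p = 0.238 with an estimated correlation), with DNAJB9 at 1.22 ± 0.04 and HSPA5, the chaperone BiP of the endoplasmic reticulum, at 0.90 ± 0.06. Of 22 NRF2 targets 16 fell and 3 rose (4.04e-04; adjusted p = 0.1 with an estimated correlation), with FTL, ferritin light chain, at -1.58 ± 0.07, NQO1 at -1.15 ± 0.05 and GCLC, of glutathione synthesis, at 0.86 ± 0.04. Of 24 interferon stimulated genes 19 fell and none rose in edgeR (1.2e-06; adjusted p = 0.104 with an estimated correlation), with IFIT1 at -3.46 ± 0.14 and GBP1 at -2.04 ± 0.07. Of 29 cell cycle genes 22 fell and 2 rose (camera adjusted p = 0.00192; adjusted p = 0.1 with an estimated correlation), with the mitotic transcription factor gene FOXM1 at -3.30 ± 0.12 and CDK1 at -2.41 ± 0.16. Ferritin genes share reads with pseudogenes, so their levels are uncertain.

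**Figure D3:**
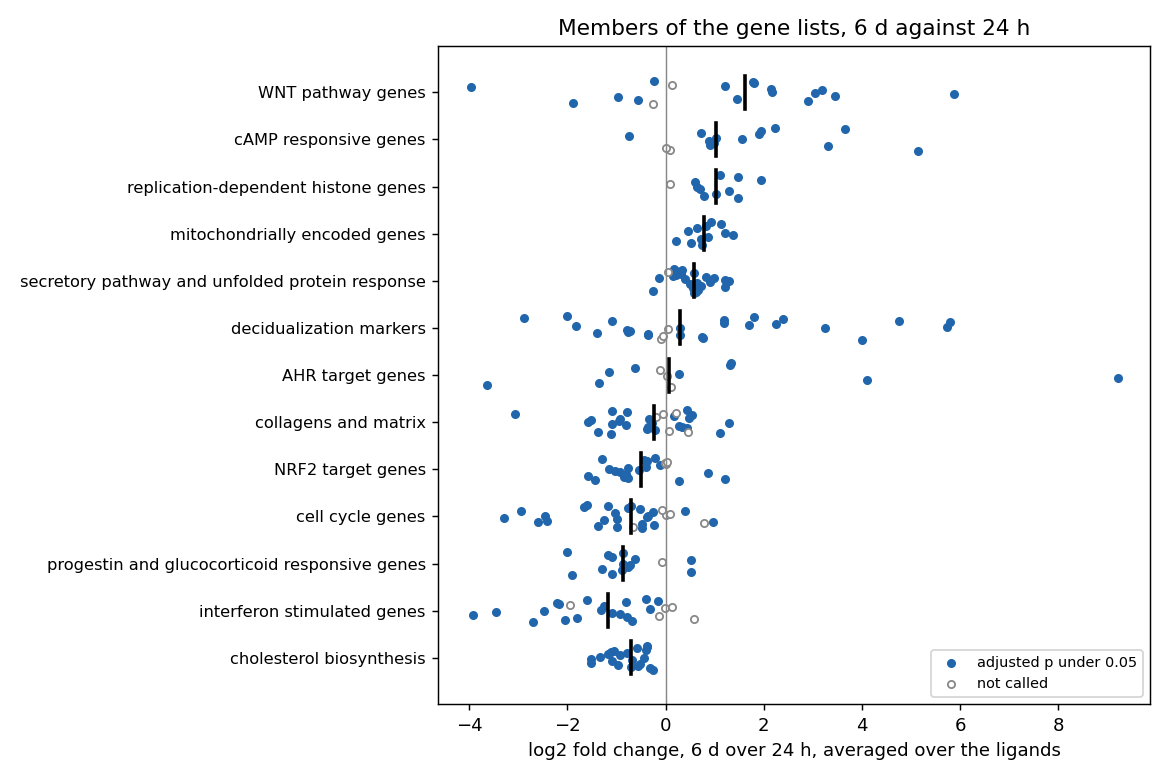
Log2 fold changes from 24 h to 6 d, averaged over the ligands, for the tested members of 13 gene lists, 1 point per gene, filled where edgeR's adjusted p was under 0.05, with the list median as a vertical bar. All 21 cholesterol genes lie below 0, and the AHR target at 9.22 is FOXQ1, which stood at 0.0095 and 0 CPM at 24 h and whose fitted value is no estimate of a fold.

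Of 15 matrix metalloproteinases and inhibitors 9 rose and 5 fell (camera adjusted p = 0.00626; adjusted p = 0.104 with an estimated correlation), with MMP7, matrilysin, at 3.38 ± 0.08 and MMP11 at 2.70 ± 0.08. Of 18 WNT pathway genes 11 rose and 5 fell (0.00192; adjusted p = 0.108 with an estimated correlation), with FZD8 at 3.46 ± 0.10 and the antagonist genes SFRP1 at 3.18 ± 0.10 and DKK1 at -1.89 ± 0.05. Of 20 complement and coagulation genes 12 rose and 5 fell (0.00392; adjusted p = 0.226 with an estimated correlation), with PLAU, urokinase, at 4.81 ± 0.09. Collagens and matrix genes did not pass limma's camera (adjusted p = 0.142), with 9 of 30 higher and 16 lower, among them COL8A1 at 1.30 ± 0.06 and FBN1, fibrillin, at -1.59 ± 0.09. Neither did AHR target genes (limma's camera adjusted p = 0.369), of which 5 of 12 rose and 4 fell. TIPARP rose by 1.34 ± 0.06 and the amino acid transporter gene SLC7A5 by 1.32 ± 0.06, while NQO1, a quinone reductase, fell (-1.15 ± 0.05). Of 17 genes of the AHR complex and its partners 7 rose and 6 fell (limma's camera adjusted p = 0.619), with ARNT at -0.38 ± 0.04 and ARNTL at 0.70 ± 0.07.

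Markers of other cell types and of RNA quality moved between the times too. Among epithelial markers EPCAM and CDH1, at 34 and 15 reads over all 10 libraries, did not pass the count filter. A rise of the tested ones therefore does not show a gain of epithelial cells. Of 6 tested epithelial markers 5 rose (camera adjusted p = 0.00361; adjusted p = 0.238 with an estimated correlation), with the keratin genes KRT19 at 2.36 ± 0.07 and KRT18 at 1.10 ± 0.07. Of 9 smooth muscle and myofibroblast markers 6 fell and 3 rose (0.0359; adjusted p = 0.372 with an estimated correlation), with ACTA2 at -1.29 ± 0.06 and TAGLN at -1.13 ± 0.06. All 12 tested mitochondrially encoded genes were higher at 6 d (0.00192; adjusted p = 0.372 with an estimated correlation), and their share of the counts was 0.949 to 1.33% in the libraries of 24 h and 1.71 to 1.94% in those of 6 d. Of 11 replication-dependent histone genes 10 were higher (2.64e-04; adjusted p = 0.1 with an estimated correlation), with HIST1H4H at 1.48 ± 0.05. Ribosomal protein genes did not pass limma's camera (adjusted p = 0.859), with 5 of 34 higher and 4 lower. The labels give no batch, so a difference in handling between the times cannot be told apart from time.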

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

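No test in this part was chosen after its result was seen. The difference between TCDD and KYN changed between 24 h and 6 d for 15 of the 31 lists by camera at the preset correlation, a test of the interaction itself, and that is what singled them out. Their median interaction, the log2 difference at 6 d minus that at 24 h, was positive for progestin and glucocorticoid responsive genes (0.23; camera adjusted p = 1.67e-11), collagens and matrix (0.16; 2.02e-07), smooth muscle and myofibroblast markers (0.23; 3.96e-06), ribosomal protein genes (0.11; 0.00106), HLA and antigen presentation (0.28; 0.0325), WNT pathway genes (0.13; 0.0335), cholesterol biosynthesis (0.04; 0.0325) and decidualization markers (0.04; 0.0489). It was negative for p53 target genes (-0.17; camera adjusted p = 0.00106), NRF2 target genes (-0.12; 0.00148), ATF4 and integrated stress response (-0.07; 0.00371), endothelial markers (-0.21, or -0.4 without a member near 0 reads; 0.0067), AHR target genes (-0.17, or -0.19 likewise; 0.00906), the AHR receptor complex and partners (-0.1; 0.0449), and tryptophan and kynurenine metabolism (-0.09; 0.0489). None of these 15 calls was kept with a correlation estimated per list or by fry, and none of the 14858 genes passed the interaction in edgeR, so the difference between the times rests on the preset correlation of 0.01. No explanation was weighed for them.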

How the results depend on the processing

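Leaving out both 24 h libraries nearer the other ligand (24hKYN 3 and 24hTCDD 2), a term for the 24 h structure and the correction for GC content were chosen only after the results were seen. The counts of genes between times kept within 1.5 times their value of 8064 with KYN, 7824 with TCDD and 9681 averaged under every alternative, with leave-one-out ranges of 6260 to 8348, 6256 to 8001 and 8778 to 9745, and all 16 genes named by size in each of these comparisons were called in every run. The counts between ligands did not hold. For the ligands at 24 h, at 6 d, averaged over times and for the interaction, in that order, edgeR gave 3, 22, 18 and 0 genes, the DESeq2 Wald test 101, 99, 177 and 61, and edgeR with no count filter 425, 206, 380 and 250. Without the filter 414 of the 425 genes at 24 h are in the filtered test as well, so most of the gain is not genes that the filter removes. The prior degrees of freedom became infinite in place of 5.68, so the shrinkage of the variances changed too. No run changed that shrinkage alone, so its share in the gain was not tested. For DESeq2 the cause was not tested. On simulated data it made 20 to 32 false calls among 196 to 227, and edgeR 9 to 16 among 176 to 211. The simulation lacked structure shared across genes, so it does not show why the counts differ in the real data. A fit of the groups compared alone gave 0 at 24 h and 259 at 6 d. It takes the filter, the normalization and the spread from those libraries only, and the cause of the change in counts was not tested. With limma-voom, DESeq2 size factors and the filter at 1 CPM the counts stayed within 1.5 times.

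With a replicate block the counts were 64, 32, 57 and 1, but whether the numbers of the count columns pair the libraries is not known. Deviations from the group means correlated between same-numbered libraries at -0.225, 0.205 and 0.311 at 24 h and at 0.055 at 6 d. Because 24hKYN 1, 24hKYN 2 and 24hTCDD 2 form a set, any pairing of the ligands at 24 h puts a pair across the sets. That favours a negative value there, so these correlations cannot decide whether the numbers pair the libraries. The best match of 24hKYN 1 was 24hTCDD 2 (0.337). By the numbers of the TPM columns the pairs of 24 h correlated at -0.163, 0.311 and 0.337, and no block on those numbers was run. The cause of the change in counts was not tested. Leaving out each library in turn gave 0 to 367 genes at 24 h, 0 to 47 at 6 d, 0 to 177 averaged and 0 to 51 for the interaction, the highest each time without 24hTCDD 2, and the cause was not tested. Without a library of 6 d the lone sample of its group is assumed to vary like the others. The correction for GC content gave 18, 90, 122 and 13, and the cause was not tested. Leaving out both libraries gave 1088, 153, 635 and 414, and the term 60, 220, 283 and 48; both select libraries on the values tested, so these counts are not evidence of a difference between the ligands. The correlation of the ligand difference at 24 h and at 6 d (r = 0.11) ran, with each library left out in turn, from -0.006 without 6dTCDD 1, where its sign reversed, to 0.132, and the cause was not tested. That of the time difference with KYN and with TCDD (0.913) ran from 0.849 to 0.915 in the same runs. Over genes of at least 2 CPM they were 0.164 and 0.964.

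None of the 3, 14 and 14 genes named by size in the ligand comparisons was called in every run, though none changed direction. Of the lists called by camera, fry lost 1 of 2 at 24 h, 7 of 9 at 6 d, 3 of 6 averaged over times, none of 16 between times and 15 of 15 for the interaction. Leaving out a library ended 5 of 9 calls at 6 d, 1 of 6 averaged, 1 of 16 between times and 9 of 15 for the interaction, and the correction for GC content 1 of 9 at 6 d and 3 of 15. Leaving out both 24hKYN 3 and 24hTCDD 2 ended 1 of 6 list calls averaged over times and 3 of 15 for the interaction. For the interaction the replicate block ended 2 of 15 list calls and DESeq2 size factors 1 of 15. The limma trend tests planned on log2 TPM, with 1 and with 0.1 added, were not run because the TPM values lack their decimal separator. The count filter left CYP1A1 and CYP1B1 untested, at 24 and 10 reads over 10 libraries, as it did CYP1A2, ALDH3A1, IDO1 and TDO2, at 1, 4, 1 and 0.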

Other observations

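The exchange of labels, the splits of the 24 h libraries, the reading of the cell cycle list for S phase and the level of AHR were tested only after the result was seen. Lists that did not pass camera between the times still held called genes. Of all 14858 tested genes 65.2% were called in this comparison, so a list count near that share says nothing particular about the list. From 24 h to 6 d, averaged over ligands, VEGFA, the vascular growth factor, rose by 2.90 ± 0.05 (log2 fold change), the glycolytic regulator PFKFB3 by 2.00 ± 0.06 and the glucose transporter SLC2A1 by 1.84 ± 0.06, while 10 of 21 genes of glycolysis and hypoxia fell and 8 rose (limma's camera adjusted p = 0.194, with a median of -0.08 but a mean of 0.2). Of 23 ATF4 and integrated stress response genes 12 rose and 8 fell (limma's camera adjusted p = 0.152), with STC2, stanniocalcin, at 2.62 ± 0.07 and DDIT4 at -1.88 ± 0.14. Of 17 p53 target genes 11 rose and 2 fell (limma's camera adjusted p = 0.0665), with GDF15 at 2.07 ± 0.08. Of 16 amino acid transporters 8 rose and 4 fell (limma's camera adjusted p = 0.324), with SLC1A4 at 0.94 ± 0.04 and SLC38A2 at -0.84 ± 0.04. Of 10 genes of tryptophan and kynurenine metabolism 3 rose and 4 fell (limma's camera adjusted p = 0.859, its direction down while median and mean were above 0), with KYNU, kynureninase, at 0.40 ± 0.07 and AADAT at -0.68 ± 0.07.

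CD274 and PDCD1LG2, the ligands of the immune checkpoint receptor PD-1, rose by 2.21 ± 0.04 and 1.92 ± 0.06, while NLRC5, an activator of HLA class I genes, fell by 1.06 ± 0.07. Over the 17 genes of HLA and antigen presentation 3 rose and 7 fell (limma's camera adjusted p = 0.703, its direction up while median and mean were below 0). Of 16 NF-kappaB response genes 4 rose and 10 fell (limma's camera adjusted p = 0.152), with NFKBIA at -1.72 ± 0.08, and of 13 cytokines and chemokines 5 rose and 6 fell (0.859, with a median of -0.05 and a mean of 0.42), with IL8 at 2.79 ± 0.08 and CXCL12 at -1.67 ± 0.05. Of 20 genes of TGF-beta and BMP response 7 rose and 9 fell (limma's camera adjusted p = 0.369, with a median of -0.07 and a mean of 0.07), with CTGF at 1.58 ± 0.05 and TGFBI at -2.78 ± 0.11. Of 6 endothelial markers 2 rose and 3 fell (limma's camera adjusted p = 0.584; median -0.86, or 0.02 without a member near 0 reads, and direction up), with KDR at 4.76 ± 0.15, and of 5 leukocyte markers 1 rose and 2 fell (0.584; median 0.13, mean -0.32), with CD163 at -2.46 ± 0.16.

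The 6 libraries of 24 h fell into 2 sets that did not follow the ligand, and an exchange of labels between 24hKYN 3 and 24hTCDD 2 was left open: over the 22 genes called at 6 d, 24hTCDD 2 minus 24hKYN 3 was 0.04 ± 0.038 (SE) in the direction of TCDD, and group means gave 0.084 ± 0.07. Across 11383 genes the ligand difference at 24 h correlated with that at 6 d at r = 0.151 as labelled. With both exchanged r was 0.015. As labelled, 8 of the 22 genes (among them HMOX1, PDK4 and LACC1) separated the 24 h libraries in their direction of 6 d. In the opposite direction 2 separated them as labelled, against 3 and 1 with both exchanged. The 22 genes were called with a spread estimated partly within the 24 h groups as labelled, which favours genes tight within them. Their separation therefore cannot decide between the labellings. The correlation alone leans toward the labels, but how genes respond at 24 h is not known apart from the labels. Depth does not account for the sets, since the gap on the first component was 26.4 after thinning all libraries to 24110046 counts. The weights of genes on the component did follow GC content (absolute Spearman rho 0.338). The GC trend of 24hTCDD 3, however, rose with GC content as in 24hKYN 1, 24hKYN 2 and 24hTCDD 2, while those of 24hKYN 3 and 24hTCDD 1 fell. With each library's GC trend removed the gap remained at 22.4 and the component held 45.4% of the variance, so GC content is not the whole cause. The 3 genes called between ligands at 24 h compare with 1466 for the highest of the other splits, the one that follows the sets (counting the real one, 2 of 10 splits reached 3, and 10 are too few for a share under 0.05). The labels give no batch and no biological explanation was tested, so an unrecorded batch could remain.

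For the ligands averaged over times chance could not be excluded, with 18 genes for the real groups, 337 for the highest of the other splits and 5 of 60 splits as large, counting the real one. No other splits were run for the ligands at 6 d alone. For time averaged over the ligands the real groups gave 9681 genes and the highest of the other splits 0. Only the real split, 1 of 100, was as large. Every other split mixes libraries of 24 h and 6 d within a group, which widens the spread and leaves few calls. The splits thus argue only against a random division of these libraries. They do not address a difference in culture or handling that went with time.

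Replication-dependent histone genes were higher at 6 d (median 1.03), though these RNAs mostly lack poly(A) tails. Whether the libraries of 6 d held more RNA without poly(A) tails stays open: the 5 tested of 37 other such RNAs had a median of -0.28, but only RN7SL2 (-0.37 ± 0.16) reached a mean of 2 CPM, none passed in edgeR, and RN7SK went the other way (0.50 ± 0.36). The median of the cell cycle list was -0.7, which argues against more cells in S phase. That histone RNAs carry poly(A) tails in cells leaving the cycle was not tested.

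CYP1A1 and CYP1B1 stayed near 0 reads with both ligands. Overlapping genes cover at most 13% of their exonic bases, so reads lost to overlap do not account for it, though other reasons for uncounted reads, such as the annotation release or the strand, were not tested. AHR stood at 25.1 CPM or more in every library, so a missing receptor transcript does not either. Whether the ligands activated AHR in these cultures could not be tested without untreated libraries.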
